A study of Mus musculus with 12 samples.

How the data were processed

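RNA was measured in hair follicle stem cells of mouse back skin by sequencing. Skin was dissociated with collagenase and trypsin, and cells were sorted by fluorescence as positive for H2BGFP, negative for Sca-1, and positive for CD34 and CD49f. H2BGFP is a green fluorescent histone, here under the keratin 14 promoter, which is active in basal keratinocytes and stem cells of the follicle. Sca-1 is the product of Ly6a, CD49f is that of Itga6 and CD34 is that of Cd34, so these 3 transcripts belong to genes used in the gate. Knockout (KO) mice carried a Cre recombinase under the same promoter and floxed Foxc1 alleles. Wild-type (WT) controls carried the floxed alleles without Cre. Per the labels, RNA was selected with oligo(dT) and libraries were made with a directional kit.

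The 12 libraries formed 4 groups. The anagen (growth phase) groups held 2 KO libraries (P29 and P31, replicates 1 and 2) and 3 WT libraries (P29, P30 and P31, replicates 1 to 3). The early telogen (resting phase) groups held 4 KO libraries (replicates 5, 1, 2 and 3) and 3 WT libraries (replicates 1, 3 and 4). Anagen WT replicate 3 was titled P31 and carried an age label of 43 days. Early telogen KO replicate 5 was titled P43 and carried an age label of 47 days. Both were placed by the table that held them. The labels do not say that replicates were separate animals, so each p-value measures the spread between samples only. Both anagen KO libraries were labelled female and 2 of the 3 anagen WT libraries male, so sex and genotype overlapped there. Xist and Ddx3y counts matched the sex label in 12 of 12 libraries.

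The deposited values were raw read counts per gene, in 1 table per stage. Per the labels, the authors aligned reads with TopHat2 to the mouse genome build mm10 and counted them with HTSeq. Versions, settings, the strand option used in counting and any sequencing batch were not given. The anagen table held 38803 genes and 5 tally lines. Of the counts in that table's libraries, including the tallies, 7.55% to 9.43% were reads in no annotated feature, 0.481% to 0.614% were ambiguous and 31.1% and 32.8% in KO and 20.1% to 25.8% in WT were reads placed at more than 1 position, so this share was higher in both anagen KO libraries than in every anagen WT library. Such reads were not counted for genes, which lowers values for genes with close copies. The early telogen table had no tally lines and held 37958 genes. Broken lines, 3 in number, were left out, and 27 gene names had been turned into dates. The tables shared 37931 names. The anagen table alone held 872 names with 3.14% to 3.41% of the anagen counts, among them 24 genes of the lists used here, such as Plk1, Postn and Pmel. These genes were left out of every comparison that used the early telogen table.

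Totals over genes ranged from 29025553 to 54482469 counts in anagen and from 2662083 (KO replicate 5) to 11821916 in early telogen. The 10 genes with most counts held 7.84% to 10.4% of a library. No pair of libraries in a group were copies of each other. Levels are given as CPM, counts scaled by a library's total over genes, as mean ± SD, and log2 fold changes as estimate ± SE from the model. Counting intervals and floors (3 counts over the group, 95% exact intervals for ratios with 1 to 3 counts) cover counting error only, since reads carried no molecular identifiers.

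Each genotype comparison was fitted within its own table, and WT early telogen against WT anagen was fitted on the 6 WT libraries. The difference of the KO effect between stages was tested as a contrast of the 4 group means over all 12 libraries. Tests used edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr (minimum count 10, minimum total 15), robust quasi-likelihood F-tests and Benjamini-Hochberg adjustment, and a gene passed at an adjusted p under 0.05. A total of 33 gene lists was tested with limma 3.58.1 camera on log2 CPM (prior count 2), with a preset correlation of 0.01 between genes and adjustment over the lists of a comparison. A list needed 3 tested members. Camera compares a list with all other genes, and camera with an estimated correlation and fry, which tests the list on its own, were run beside it. Some lists share members, such as Bmp2, Fgf18 and Wif1.

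The comparisons, tests, gene lists, naming rule and alternatives were chosen before the data were examined, except where stated. Named genes were, per comparison and direction, the 10 of largest absolute log2 fold change (5 for the difference between stages) among those that passed, with at least 5 CPM in 1 group and, outside the difference between stages, no overlap between groups. Sex-linked genes, Foxc1 and provisional names were left out of these sets. To them were added 4 members per list of smallest p where 4 or more passed, otherwise the members that passed, otherwise 2, and a fixed set of genes known from hair follicle stem cells. In anagen, where no gene passed, the rule was applied to the fit of all 12 libraries, a step taken after that result was seen.

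Positions are from the GENCODE M21 annotation of the same build. It held 232 of the 236 named genes, and 60 of these overlapped a gene on the opposite strand, so their counts depend on the strand option. Among those 60 were Kif20a, Ube2c, Cd34, Gli1, Camk4, Fchsd1 and Bmp6.

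The steps were tested on simulated data made from the libraries' own spread, with 100 changed genes per fold size. In anagen 6 of 100 genes changed 2-fold and 64 of 100 changed 4-fold were recovered, with 6 false calls. In early telogen 24 and 72 of 100 were recovered, with 8 false calls. For the difference between stages the numbers were 3 and 33, with 3 false calls, and for WT stage 21 and 64, with 5 false calls. The anagen comparison and the test of the difference therefore had the least power for 2-fold changes. The early telogen and WT stage comparisons also missed most of them. DESeq2 recovered more genes and made 24 to 31 false calls in each.

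Alternatives were DESeq2 1.42.0 size factors or its Wald test, no filter on low counts, a filter at 5 CPM, sex as a covariate, quasi-likelihood without robust estimation, an added log2 fold change of at least 1, all 12 libraries in 1 fit, replicate number or day as a block, and each library left out in turn. Early telogen without KO replicate 2 and WT replicate 3 was added after seeing the data. Foxc2 had too few counts to be tested. Some genes that passed are not reported here by name, and the counts of genes include them.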

Results

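The series measured how loss of Foxc1, a forkhead transcription factor, changed gene expression in hair follicle stem cells during anagen and early telogen. Foxc1 (ENSMUSG00000050295.4) lies on chromosome 13 from 31806633 to 31812476 on the plus strand and has a single exon, with the coding sequence from 31807208 to 31808866 and untranslated sequence on both sides. In anagen, Foxc1 was at 0.241 ± 0.0494 CPM in KO (n = 2) and 65.9 ± 43.8 CPM in WT (n = 3), a log2 fold change of -8.19 ± 0.81 with an edgeR adjusted p of 0.0522. The fit of all 12 libraries gave an edgeR adjusted p of 0.000248. Each anagen KO library held 8 Foxc1 counts. In early telogen Foxc1 fell in KO, to 1.86 ± 1.03 CPM (n = 4) from 54.7 ± 9.48 CPM (n = 3), by 4.99 on the log2 scale (edgeR adjusted p = 8.63e-06). Every KO library lay below every WT library in both stages. The KO log2 fold changes differed by 3.16 between the stages (edgeR adjusted p = 0.220). This difference was called by DESeq2 (adjusted p = 0.00431), without a filter on low counts (edgeR adjusted p = 1.99e-08) and without anagen WT replicate 1 (edgeR adjusted p = 0.0425), so whether depletion differed was left open.

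**Figure D1:**
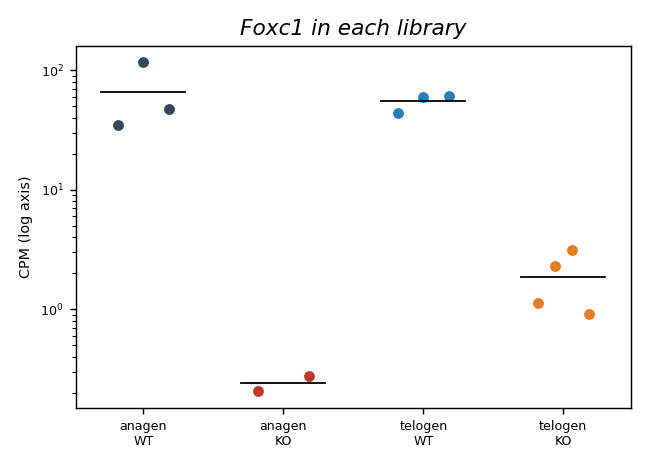
Foxc1 level in each library in CPM on a log axis, by group, with points for libraries and lines for group means. The KO libraries sit between 0.206 and 3.11 CPM and the WT libraries between 34.6 and 115.9 CPM.

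In early telogen, genes of cell division rose in KO stem cells. Mki67, the proliferation marker encoding Ki-67 (chromosome 7, 135689784 to 135716361), was at 48.2 ± 1.47 CPM in KO (n = 4) and 7.57 ± 1.66 CPM in WT (n = 3), a log2 fold change of 2.52 ± 0.22. The mitotic cyclin-dependent kinase Cdk1 rose by 2.67, the spindle factor Tpx2 by 2.96, the mitotic kinesin Kif20a by 3.14 and the ubiquitin-conjugating enzyme Ube2c by 2.85 on the log2 scale. Wif1, a secreted inhibitor of WNT ligands (chromosome 10, 121033960 to 121100650), rose by 2.47 ± 0.26, to 175 ± 37.3 CPM from 28.2 ± 10.8 CPM. Cd34, a surface marker of bulge stem cells and a gene of the gate (chromosome 1, 194938819 to 194961279), fell by 1.20 ± 0.21 on the log2 scale, to 372 ± 30.6 CPM from 760 ± 102 CPM. The edgeR adjusted p was 9.65e-05 for Mki67, 0.000669 for Wif1 and 0.0212 for Cd34. The other gate genes did not pass, with log2 fold changes of -0.16 for Itga6 and 1.81 for Ly6a.

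Of 12030 genes tested in early telogen, 60 rose and 55 fell in KO. Among the 10 named for the largest rise, besides those above, were Mad2l1 of the spindle checkpoint (2.54), Ect2 (2.52) and Iqgap3 (2.66), the proton pump subunit Atp6v1b1 (3.10) and D17H6S56E-5 (2.62). The kainate receptor subunit Grik1 fell to 2 counts over the 4 KO libraries, a ratio of WT to KO of 248 with a counting interval of 68.3 to 2058. Falls on the log2 scale were -4.34 ± 0.38 for the calcium/calmodulin-dependent kinase Camk4, -3.18 ± 0.43 for the cytokine receptor Il31ra, -2.90 ± 0.51 for the potassium channel Kcnma1 and -2.62 ± 0.43 for the calcium pump Atp2a3. Cyp2b10 (-2.48), Gpc6 (-2.34), Gabre (-2.32), Fmn1 (-2.09) and Fchsd1 (-1.97) fell too, with Fchsd1 at 41.4 ± 5.67 CPM in KO and 144 ± 18.5 CPM in WT. A lack of overlap between KO and WT libraries was a condition for naming these genes, so it is no result. Several factors tied to stem cell quiescence did not pass, with log2 fold changes of -1.80 for Bmp6 (edgeR adjusted p = 0.120), -1.46 for Fgf18, -0.78 for Bmp2, -0.53 for Foxp1 and -0.22 for Nfatc1 (edgeR adjusted p = 0.758). The stem cell genes Sox9 (-0.75), Krt15 (-0.23), Lhx2 (-0.35), Lgr5 (0.14) and Tcf7l1 (-0.20) did not pass either, nor did Cdkn1a (-0.74), Ccnd1 (0.40), Ccnd2 (0.44), Cdh1 (-0.23), Cdh3 (-0.57) and Cldn1 (0.67). Calls for Mki67, Top2a, Anln, Tpx2, Wif1, Grik1, Camk4, Gpc6, Fmn1, Fchsd1 and Foxc1 held with each of the 7 libraries left out in turn, and the call for Cd34 was lost without KO replicate 5 (edgeR adjusted p = 0.0551), KO replicate 1 (0.0692), WT replicate 3 (0.125) or WT replicate 4 (0.0814). Of the other named genes, Il31ra lost its call without KO replicate 2 (0.0724) or WT replicate 3 (0.0516), and the rest without KO replicate 5 (0.0523 for Cyp2b10 to 0.119 for Kif20a) and some other libraries. The counts of genes that rose and fell were 9 and 15 without KO replicate 5, 26 and 21 without KO replicate 1, 29 and 46 without WT replicate 1, 9 and 10 without WT replicate 3, and 25 and 19 without WT replicate 4. The fit of all 12 libraries called 12 and 27 and did not call Mki67 (edgeR adjusted p = 0.148), while DESeq2 called 217 and 182.

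**Figure D2:**
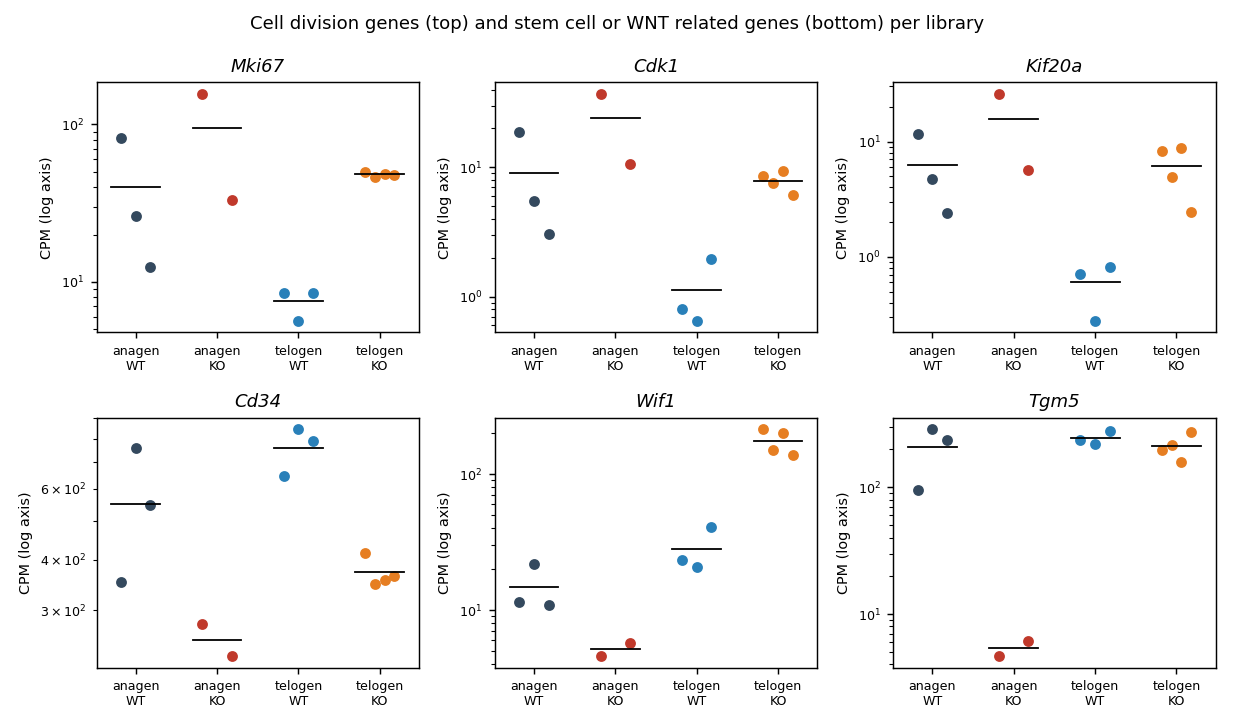
Levels of Mki67, Cdk1, Kif20a, Cd34, Wif1 and Tgm5 in each library in CPM on log axes, by group, with points for libraries and lines for group means. In early telogen the means of Mki67 are 48.2 CPM in KO and 7.57 CPM in WT.

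Of the 32 gene lists tested in early telogen, camera called 5 higher and 7 lower in KO. Of 29 mitosis genes, 12 rose, 0 fell and 17 did not pass, and 25 rose when adjusted over the list alone. Their median log2 fold change was 2.28, and Top2a (2.34) and Anln (2.03) were among those that rose. The camera adjusted p was 4.97e-33 (adjusted p = 0.165 with an estimated correlation), and the mitosis list was the only list that fry called (adjusted p = 0.00644). The list stayed called without any 1 library, with 4 to 9 members that rose, and the fit of all 12 libraries called 0 members. Of 28 DNA replication genes, the helicase subunit Mcm5 rose (1.25 ± 0.25) and 27 did not pass, 9 rose adjusted over the list alone, and 25 were positive (camera adjusted p = 1.01e-07; adjusted p = 0.380 with an estimated correlation). The call for Mcm5 was lost without any 1 of the 7 libraries (edgeR adjusted p of 0.0540 to 0.182).

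Of 23 stem cell markers, Cd34 fell and 22 did not pass, 1 fell adjusted over the list alone, and 22 had negative log2 fold changes with a median of -0.35. The camera adjusted p was 4.26e-06 (adjusted p = 0.380 with an estimated correlation). A further 6 lists were called lower by camera, though not with an estimated correlation (adjusted p of 0.569 for cell-cell adhesion and 0.553 for the others). Of 21 quiescence factors Wif1 rose and 20 did not pass, with 1 higher and 2 lower adjusted over the list alone, and the list as a whole was called lower (camera adjusted p = 0.0367). The BMP and SMAD pathway list (0 of 24 passed) and the BMP response list (0 of 11 passed) were called lower, with medians of -0.18 and -0.35, camera adjusted p of 0.0245 and 0.0188, and 0 members of either adjusted over the list alone. Examples were Bmp6 and the BMP target Id2 (-0.62). Among 26 cell-cell adhesion genes the desmosomal cadherin Dsg2 rose (1.02 ± 0.19) and 25 did not pass, 1 was higher and 2 lower adjusted over the list alone, and the list was called lower (camera adjusted p = 0.0188). Dsg2 lost its call without KO replicate 5 (edgeR adjusted p = 0.0672) and 4 other libraries. Of 30 cell-matrix adhesion genes 0 passed, 1 was higher and 4 were lower adjusted over the list alone, and the median was -0.38 (camera adjusted p = 0.00446), with the integrin subunit Itga5 at -0.96. The dissociation response list of stress and immediate early genes was also called lower (0 of 22 passed, 4 lower adjusted over the list alone, camera adjusted p = 0.00164), with Btg2 at -1.09. Without WT replicate 3, the quiescence factors, the BMP and SMAD pathway, the BMP response, cell-cell adhesion and the dissociation response were no longer called (camera adjusted p of 0.0572 to 0.224). Calls also ended for the quiescence factors without any KO replicate but 5, for the BMP and SMAD pathway without KO replicate 2 or 3, for the BMP response without KO replicate 3, and without WT replicate 4 for the quiescence factors, the BMP and SMAD pathway and cell-cell adhesion (camera adjusted p of 0.0503 to 0.119).

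Markers of other cell types also differed in early telogen. Of 6 melanocyte genes, Dct, a pigment synthesis enzyme, rose (2.34 ± 0.43) and 5 did not pass, with 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00287). Dct lost its call without KO replicate 5 (edgeR adjusted p = 0.0765) and 4 other libraries. The immune cell list (0 of 13 passed, 12 positive, median 0.85) and the endothelial cell list (0 of 10 passed, 10 positive, median 0.46) were called higher, each with a camera adjusted p of 0.00446 and 0 members adjusted over the list alone. With an estimated correlation the adjusted p was 0.380 for melanocyte and 0.553 for the other two lists. WT replicate 3 stood apart, at -0.38 mean log2 CPM for the endothelial list against 1.67 and 1.75 in the other WT libraries, and at 3.93 for epidermal differentiation against 5.68 and 6.15. The melanocyte call was lost without KO replicate 3 (camera adjusted p = 0.0710), the immune call without WT replicate 4 (0.0545) and the endothelial call without WT replicate 3 (0.396). KO replicate 2 stood apart with 56.0 CPM of Ly6a and the highest fibroblast mean of 5.89 against 3.61 to 4.93 in the other KO libraries. Without KO replicate 2 and WT replicate 3, 25 genes rose and 22 fell, 40 of them shared with the full set in the same direction, and 5 mitosis genes rose, while the mitosis, DNA replication, stem cell marker and melanocyte lists stayed called.

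The remaining 20 lists were not called in early telogen, with camera adjusted p from 0.0583 to 0.976. Among these, Gli1 (1.16 ± 0.20, to 94.7 from 37.7 CPM), a transcriptional target of hedgehog signalling, rose among the SHH pathway genes and passed adjusted over the list alone. The proteasome subunit Psmb8 rose (1.60) among 13 interferon response genes, with 2 higher adjusted over the list alone, and the interleukin-1 receptor antagonist Il1rn rose (1.17) among 14 wound keratinocyte genes, with 2 higher and 1 lower. Wif1 was the only 1 of 6 WNT antagonists to pass. Sbsn fell by 1.01 on the log2 scale among 23 epidermal differentiation genes, with 1 higher and 2 lower adjusted over the list alone, and the glucose transporter Slc2a1 fell to 432 from 769 CPM among 18 hypoxia and glycolysis genes, with 2 higher and 1 lower. No member passed in the lists for WNT response, NOTCH pathway, TGFB response, cell cycle inhibitors, hair germ, matrix and inner root sheath and hair shaft, companion layer and inner bulge, isthmus and infundibulum, sebaceous gland, p53 targets, sterol synthesis, fibroblast and dermal papilla, muscle, or Schwann cell and adipocyte. Adjusted over the list alone, 3 companion layer, 1 WNT response and 1 sterol synthesis gene were lower. In the sebaceous gland list the median and mean were negative and the test pointed up, and in the wound keratinocyte list the median alone was negative. The calls for Gli1, Psmb8, Il1rn, Sbsn and Slc2a1 were lost without KO replicate 5 (edgeR adjusted p of 0.0672 to 0.122) or WT replicate 3 (0.0802 to 0.273), and some also without other libraries.

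**Figure D3:**
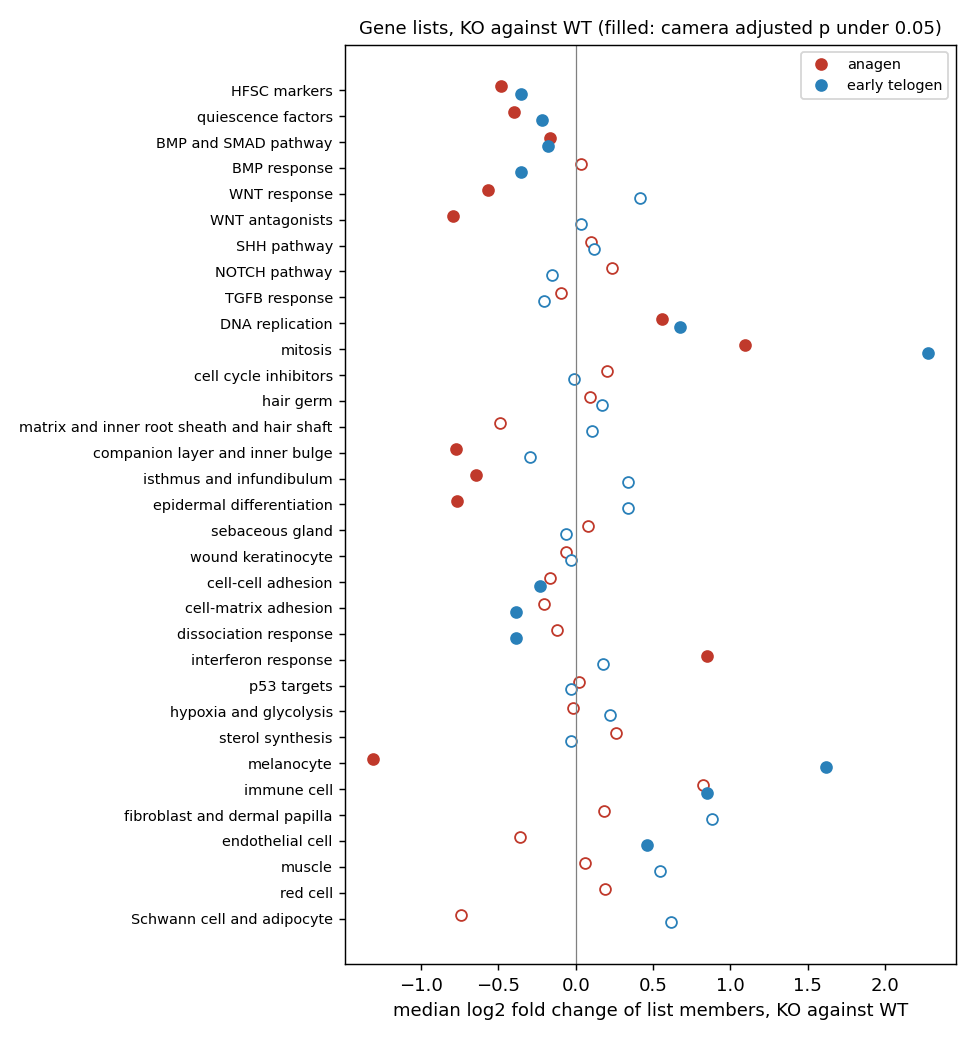
Median log2 fold change of KO against WT over the members of each gene list, with red points for anagen and blue points for early telogen, filled where the camera adjusted p was under 0.05. The mitosis list lies at 1.09 in anagen and 2.28 in early telogen, and the melanocyte list at -1.31 and 1.62.

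In anagen the largest differences between KO and WT were in genes that were lower in KO. The transglutaminase gene Tgm5 (chromosome 2, 121046111 to 121085841) was at 5.38 ± 1.06 CPM in KO (n = 2) and 207 ± 99.9 CPM in WT (n = 3), a log2 fold change of -5.36 ± 0.59. The keratin gene Krt24 was at 15.1 ± 0.681 against 359 ± 263 CPM, and Gfra1, a GDNF co-receptor, at 7.96 ± 0.241 against 144 ± 98.4 CPM. Bmp2, a BMP ligand, was at 10.4 ± 2.10 against 47.0 ± 4.36 CPM, a log2 fold change of -2.26 ± 0.23, and the bulge keratin Krt15 was at 1723 ± 663 against 7003 ± 2325 CPM. Mki67 was at 94.7 ± 87.2 against 40.0 ± 36.5 CPM, a log2 fold change of 1.16 ± 0.87 (edgeR adjusted p = 0.720). With the day of the title as a block, the log2 fold change of Mki67 was 1.09 (edgeR adjusted p = 0.0384). That fit leaves 1 residual degree of freedom, and the age labels of its P31 pair differ.

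Of the anagen counts including the tallies, 31.1% and 32.8% in KO and 20.1% to 25.8% in WT were of reads placed at more than 1 position. These were not counted for genes. Within the 5 anagen libraries, edgeR called 0 of 14409 genes, with 1456 at an unadjusted p under 0.05, of which 968 were lower in KO. The smallest edgeR adjusted p was 0.0522, shared by 18 genes. Of these 17 were lower, among them Foxc1, Tgm5, Bmp2, Atp2a3 and Ngef, and 1 was higher, the protease inhibitor Serpine2 (1.70 ± 0.19), named after its values were seen. DESeq2 called 91 higher and 408 lower, and edgeR with all 12 libraries in 1 fit called 7 higher and 147 lower. With the day of the title as a block, which leaves 1 residual degree of freedom, edgeR called 46 higher, 4 of them mitosis genes, and 207 lower, with Foxc1 at an adjusted p of 0.000169. The 7 that rose in the fit of all 12 libraries were Pcp4 (3.68), the glutathione reductase gene Gsr (2.94), the phosphatase gene Dusp4 (1.85), Lgals9 (1.33), the interferon regulator Irf7 (1.23), Mbd1 (1.08) and Insig2 (0.96), given as log2 fold changes within anagen. Its 10 largest falls were Sphkap (-7.37), Atp2a3 (-6.79), Tgm5, Adcy1 (-5.06), Myoc (-4.79), Krt24 (-4.67), Ngef (-4.57), Chat (-4.56), Nptx1 (-4.37) and Gfra1 (-4.28). The fit of all 12 libraries also called lower Bmp2 (edgeR adjusted p = 0.00798), Krt15 (0.0101), Nfatc1 (0.0289, log2 fold change -1.37) and Fgf18 (0.0177, log2 fold change -3.77). It did not call Foxp1 (-0.91), Bmp6 (-1.21), Lhx2 (-0.66), Sox9 (0.23), Tcf7l1 (0.02), Lgr5 (0.19), Cdkn1a (-0.43), Ccnd1 (0.47), Ccnd2 (-0.37), Cdh1 (-0.35), Cdh3 (0.35), Cldn1 (-0.10) or the gate genes Cd34 (-1.22), Itga6 (-0.38) and Ly6a (0.00). Without WT replicate 1 the anagen libraries alone gave 14 higher and 81 lower, and without WT replicate 2 they gave 0 higher and 1 lower.

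Of 33 lists in anagen, camera called 3 higher and 9 lower in KO, and 0 members of any list passed over all genes in the anagen libraries alone. With the day of the title as a block camera called 11 lists, of which 9 were among these 12 in the same direction. All 30 mitosis genes had positive log2 fold changes, with a median of 1.09 (camera adjusted p = 3.57e-05), and Cenpa, a centromere histone, was at 1.19 ± 0.45. Of 30 DNA replication genes 27 were positive, with a median of 0.56 (camera adjusted p = 0.000208) and the ribonucleotide reductase subunit Rrm2 at 0.77. Of 18 interferon response genes 17 were positive, with a median of 0.85 (camera adjusted p = 9.68e-05), and Irf7 and Isg15 were at 1.23 and 1.21. In each of these 3 lists the adjusted p was 0.763 with an estimated correlation, and 0 members passed adjusted over the list alone. The mean log2 CPM of the mitosis list was 4.68 in KO and 3.85 in WT titled P29, and 2.53 in the P30 WT library. It was 2.90 in KO and 1.63 in WT titled P31, but that WT library carried an age label of 43 days. That library was also labelled male and the KO library female, so this pair may not be matched. With sex as a covariate the mitosis list pointed down (camera adjusted p = 0.941), and without KO replicate 1 the camera adjusted p was 0.497 for the mitosis list and for DNA replication.

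Camera called 9 lists lower in anagen KO, but none of them with an estimated correlation (adjusted p = 0.763 for each), and fry called 0. They included 24 stem cell markers, of which 7 were lower adjusted over the list alone and 17 had negative log2 fold changes (median -0.48, camera adjusted p = 0.000200). Of 22 quiescence factors 5 were lower adjusted over the list alone (camera adjusted p = 0.0279), among them Bmp2 and Fgf18. Of 25 BMP and SMAD pathway genes 6 were lower (camera adjusted p = 0.0114), including the BMP antagonist Nog at -3.50. WNT response (1 of 16 lower, camera adjusted p = 0.00572, Axin2 at -1.13) and WNT antagonists (2 of 9 lower, camera adjusted p = 0.0144, Sostdc1 and Wif1 at -1.63 and -1.61) were called as well. So were companion layer and inner bulge (1 of 10 lower, camera adjusted p = 0.0266) and isthmus and infundibulum (2 of 11 lower, camera adjusted p = 0.0248, with the stem cell receptor Lgr6 at -2.37). Epidermal differentiation was lower too (4 of 23, camera adjusted p = 0.000200, Dmkn at -2.14 and Klk7 at -1.39), as was melanocyte (1 of 10, camera adjusted p = 0.00965, Mitf at -3.33), where all 10 genes were negative. Single libraries ended calls here for the quiescence factors (KO replicate 1 or WT replicate 3), BMP and SMAD pathway (WT replicate 3), isthmus (KO replicate 1 or WT replicate 3), companion layer (WT replicate 2 or KO replicate 2), melanocyte (KO replicate 1 or WT replicate 2) and DNA replication (KO replicate 1 or WT replicate 3), with camera adjusted p from 0.0695 to 0.497.

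The other 21 lists were not called in anagen, with camera adjusted p from 0.0518 for sterol synthesis to 0.880 for p53 targets. Adjusted over the list alone, BMP response had 2 lower (Smad9 at -3.78), SHH pathway 2 lower (Cdon and Hhip at -1.94 and -3.61), hair germ 1 lower, cell-cell adhesion 2 lower (Cadm1 at -2.21), cell-matrix adhesion 1 higher and 4 lower (Lamb3 at -1.28), hypoxia and glycolysis 1 lower (Hk2 at -1.36), and Schwann cell and adipocyte 1 higher and 1 lower. The immune cell list had a median of 0.82 (camera adjusted p = 0.0913), the endothelial list -0.36 (0.134), the fibroblast and dermal papilla list 0.19 (0.589), muscle 0.06 (0.589) and red cell 0.19 (0.830). Median and test differed in sign for BMP response, SHH pathway, hair germ, p53 targets and red cell.

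The KO effects in the 2 stages, which share no library, went the same way more often than not. Of the 60 genes that rose in early telogen, 50 had a positive log2 fold change in anagen (83.3%, against 50.8% of all genes tested in both), 7 of them at an unadjusted p under 0.05. Of the 54 that fell, Foxc1 left out, 48 were negative in anagen (88.9% against 49.2%), 36 of them at an unadjusted p under 0.05. Atp2a3 was named in both stages. Across 11924 genes the log2 fold changes had a Pearson r of 0.310 and a Spearman rho of 0.287. This is a relation across genes, which are not independent replicates, and Foxc1 and the sex-linked genes were left out of it.

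A direct test of the difference found genes whose KO effect was not the same in the 2 stages. Wif1 had a log2 fold change of -1.61 in anagen and 2.47 in early telogen, a difference of 4.06 ± 0.48 (edgeR adjusted p = 0.00585). Tgm5 had -5.36 in anagen and -0.35 in early telogen, a difference of 4.99 ± 0.58 (edgeR adjusted p = 0.00585). Krt24 (-4.67 and -0.51), Serpinb11 (-3.05 and 0.54) and Chat, the choline acetyltransferase gene (-4.56 and -1.03), likewise had a lower log2 fold change in anagen than in early telogen, each with an edgeR adjusted p of 0.0229 for the difference. In the other direction, Enc1 (0.61 and -1.76) and the lysosomal protease gene Ctsl (0.47 and -1.36) differed by -2.39 and -1.86. Of 13193 genes tested, 17 had a higher and 2 a lower effect in early telogen, and the other 12 differences ranged from 1.92 to 3.17. Mki67 did not pass (difference 1.33 ± 0.95, edgeR adjusted p = 0.921).

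Of 33 lists, camera called 7 with a higher and 1 with a lower KO effect in early telogen than in anagen. These were mitosis (0 of 29 members passed, median 1.13, camera adjusted p = 2.38e-05), melanocyte (0 of 9, median 3.50, 6.98e-09), endothelial cell (0 of 11, median 1.03, 0.000361), epidermal differentiation (0 of 24, median 1.27, 0.000509), WNT response (0 of 16, median 0.79, 0.00325), Schwann cell and adipocyte (0 of 5, median 1.87, 0.00325) and isthmus and infundibulum (Lgr6 of 11, median 1.06, 0.00965). Sterol synthesis was lower (0 of 19, median -0.28, 0.0198). Adjusted over the list alone, 6 melanocyte, 2 WNT response, 1 epidermal differentiation, 1 isthmus and 1 Schwann cell and adipocyte gene had a higher effect. With an estimated correlation the adjusted p ranged from 0.233 to 0.682. The other 25 lists had camera adjusted p from 0.0571 to 0.990. In 6 of them, the stem cell markers, quiescence factors, BMP response, TGFB response, cell-cell adhesion and cell-matrix adhesion lists, median, mean and test differed in sign. The melanocyte list was called lower in anagen KO and higher in early telogen KO, beside the genes above. Neither call held with an estimated correlation (camera adjusted p = 0.763 and 0.380), and each was lost without some single libraries.

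Calls of the difference depended on single libraries. The counts of higher and lower effects were 0 and 1 without anagen KO replicate 1, 0 and 0 without anagen KO replicate 2 (775 at an unadjusted p under 0.05), 51 and 4 without anagen WT replicate 1, and 13 and 0 without anagen WT replicate 2 or 3. They were 7 and 0 without early telogen KO replicate 5 or WT replicate 1, 8 and 0 without KO replicate 3, 12 and 1 without KO replicate 1, 2 and 0 without WT replicate 3, and 3 and 0 without WT replicate 4. Wif1 and Tgm5 passed with each library left out other than anagen KO replicate 1 (edgeR adjusted p = 0.0518 for both) and anagen KO replicate 2 (0.0747 for both). Krt24, Serpinb11, Chat, Enc1, Ctsl and Lgr6 were less firm. Each lost its call without early telogen KO replicate 3 or 5, or WT replicate 1, 3 or 4, and without some anagen libraries. Without early telogen WT replicate 3 the edgeR adjusted p ranged from 0.0606 for Chat to 0.131 for Ctsl. DESeq2 called 131 and 17. The call of the mitosis list ended without anagen KO replicate 2 (camera adjusted p = 0.414), that of isthmus without anagen KO replicate 1 (0.0659), anagen WT replicate 3 (0.0695) or early telogen KO replicate 3 (0.0592), and that of sterol synthesis without anagen KO replicate 2 (0.0637), anagen WT replicate 3 (0.201), early telogen KO replicate 2 (0.0810) or WT replicate 4 (0.243).

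**Figure D4:**
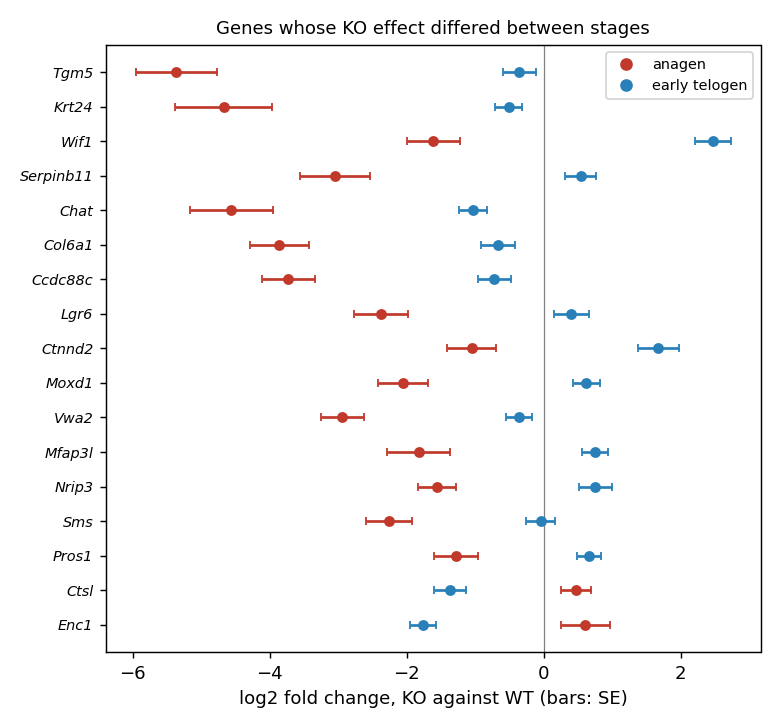
Log2 fold change of KO against WT for genes whose effect differed between stages, with red points for anagen, blue points for early telogen and bars for SE. Wif1 lies at -1.61 in anagen and 2.47 in early telogen, and Tgm5 at -5.36 and -0.35.

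In WT cells 12 of 27 cell-cell adhesion genes rose, and 14 of 20 hair shaft and 15 of 29 mitosis genes fell, from anagen to early telogen. With single libraries left out, 7 to 20 mitosis genes fell. Camera called these 3 lists, but none with an estimated correlation (adjusted p = 0.933 for each), and fry called the first and second but not the mitosis list (adjusted p = 0.130). Bmp2 rose to 282 ± 9.78 from 47.0 ± 4.36 CPM (n = 3 each), a log2 fold change of 2.68 ± 0.17. Nfatc1 (1.01), Foxp1 (0.99), Bmp6 (0.92) and the cell cycle inhibitor Cdkn1a (0.81) rose as well, as did Fgf18 (edgeR adjusted p = 0.0312). Ptgs2, a prostaglandin synthase (chromosome 1, 150100031 to 150108227), rose to 3414 ± 899 from 260 ± 216 CPM, and the WNT ligand Wnt11 to 166 ± 31.4 from 13.6 ± 3.05 CPM. The hair keratin Krt35 was at 0 counts in early telogen WT, at least 356-fold lower, and the inner root sheath keratin Krt71 fell by 4.73 ± 0.42 on the log2 scale. Stage cannot be told apart from the table, its annotation, its depth or any sequencing batch, since each stage came in its own table. The share of other cells in the sort may also have differed between stages, and it was not measured. Genes of hair matrix and shaft cells were among those that fell. Of 7 melanocyte genes 3 fell and 1 rose, in a list that was not called (camera adjusted p = 0.169). The falls, those of mitosis genes included, therefore cannot be placed in the stem cells alone.

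Of 12718 genes tested by WT stage, 1724 rose and 2024 fell. Cck (4.39), Cpa4 (3.55), Dsg1b (3.36), Lox (3.55), Calr3 (3.52) and Sncg (3.29) were among the 10 largest rises, as were the pseudogenes Rps10-ps1 (7.20) and Rps19-ps6 (6.46). The 10 named for the largest falls had 0 counts in early telogen WT, with a floor of 3 counts over the group or 0.107 CPM. They were at least 1197-fold (mmu-mir-6236), 358-fold (Hist1h2bm), 121-fold (Krt83), 94.3-fold (Padi3), 94.1-fold (Dio3), 79.1-fold (Krtap8-1), 76.6-fold (Trf), 75.3-fold (Krtap7-1) and 64.5-fold (Krt33a) lower, besides Krt35. Foxc1 itself did not pass by stage in WT (-0.18, edgeR adjusted p = 0.804), and Mki67 did not pass (-2.33, edgeR adjusted p = 0.0510). Tcf7l1 fell by 0.76, and Lhx2 (-0.11), Sox9 (0.57), Lgr5 (0.45), Krt15 (0.44), Ccnd1 (-0.02), Ccnd2 (0.02), Cdh3 (-0.51) and the gate genes Cd34 (0.55), Itga6 (0.14) and Ly6a (0.02) did not pass. The counts were 1120 and 1275 without WT replicate 3 of early telogen, and 1055 and 1257 without WT replicate 4.

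Camera called 3 lists higher and 3 lower in early telogen WT. Of 24 BMP and SMAD pathway genes, 8 rose, 1 fell and 15 did not pass, with 10 and 2 adjusted over the list alone (camera adjusted p = 0.0360), Bmp2 among those that rose. Of 16 TGFB response genes 9 rose and 3 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.0360), with Ltbp2 at 2.44 and Cyr61 at 1.82. Of 27 cell-cell adhesion genes 12 rose and 2 fell, with 13 and 2 adjusted over the list alone (camera adjusted p = 0.0244), among them Dsp (1.63), Dsg3 (1.58), Cldn1 (0.83) and Cdh1 (0.68). Of 29 mitosis genes 0 rose and 15 fell, 24 adjusted over the list alone (camera adjusted p = 6.00e-06), such as Cenpa (-3.11) and Ube2c (-3.57). The number that fell ranged from 7 without early telogen WT replicate 3 to 20 without anagen WT replicate 3. It was 3 with a filter at 5 CPM and 22 in the fit of all 12 libraries. Of 28 DNA replication genes 2 rose and 7 fell, with 2 and 8 adjusted over the list alone (camera adjusted p = 0.0494), among them Tk1 (-2.71) and Rfc4 (-1.45). Of 20 matrix, inner root sheath and hair shaft genes 14 fell, all 14 also adjusted over the list alone (camera adjusted p = 6.00e-06), Krt71 and Krt35 among them. With an estimated correlation the adjusted p ranged from 0.933 to 0.989, and fry called the hair shaft list and the cell-cell adhesion list. Without single libraries the calls ended for BMP and SMAD pathway (anagen WT replicate 1 or 2, early telogen WT replicate 3 or 4), TGFB response (anagen WT replicate 1 or 2) and DNA replication (any library but anagen WT replicate 3), with camera adjusted p from 0.0605 to 0.250.

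The other 27 lists were not called by WT stage, with camera adjusted p from 0.0918 to 0.990. Their members that passed included Sfrp1 (-1.68), Foxp1 and Nfatc1 among 23 stem cell markers (5 rose, 5 fell), Bmp2 among 22 quiescence factors (7 rose, 1 fell), Sox4 (-4.35) among 16 WNT response genes (2 rose, 1 fell), and Hk2 (2.43) and Slc2a1 (0.98) among 18 hypoxia and glycolysis genes (5 rose, 4 fell). Of 7 melanocyte genes 1 rose and 3 fell, with Dct at -4.17 and Tyr at 1 count in early telogen WT against 553 counts in anagen WT. Of 12 fibroblast and dermal papilla genes 3 rose and 1 fell (camera adjusted p = 0.0918, the lowest of these lists), and 0 of 15 immune cell and 1 of 11 endothelial cell genes passed. Median, mean and test differed in sign for WNT response, WNT antagonists, SHH pathway, cell cycle inhibitors, wound keratinocyte, sebaceous gland, cell-matrix adhesion, p53 targets, sterol synthesis and endothelial cell.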

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

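The tests of single libraries and of other cell types for the mitosis genes were chosen after the result was seen, and the count of splits was planned. In early telogen 12 of 29 mitosis genes rose in KO and 17 did not pass, and camera called the list, but not with an estimated correlation (adjusted p = 0.165), and the fit of all 12 libraries called 0 members. The tables argue against 1 library as the cause, since the lowest KO list mean lay 1.49 log2 CPM above the highest WT list mean. Other cells in the sort stay open, although the gate (H2BGFP under the keratin 14 promoter, CD34 and CD49f) is meant to remove cells outside the epithelium: the lowest KO library lay above the highest WT library for melanocytes and endothelial cells (gaps of 0.697 and 0.0613, less than the WT ranges of 0.884 and 2.13), while KO and WT libraries overlapped for immune, fibroblast and epidermal cells (the highest of the 3 gaps was -0.643, and camera called the immune list higher in KO) and for hair matrix and shaft cells (-0.499), and hair cycle timing of the mice was not tested. A ratio of the gain in melanocyte CPM to that in mitosis CPM (highest -0.0150, or 0.145 without Mitf) decides nothing, since it assumes a melanocyte profile that was not measured.

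Of 35 splits of the 7 early telogen libraries into 4 and 3, 1 gave as many genes as the real one, the real split itself with 115 genes. The highest other split gave 2, which argues against chance. It does not exclude chance, since 1 of 35 is the lowest share that these libraries can give. Every other split also mixes KO with WT libraries, which widens the spread within its groups. The WT stage comparison gave 3748 genes and the highest of the other splits gave 4. Its 6 libraries make 10 splits, of which 1, the real one, gave as many, and 10 splits are too few for a share under 0.05.

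Within early telogen KO, the group of 4, the highest or lowest library stood far from the other 3 in 10 of 119 tests of list means and gene levels by Dixon's criterion, where chance gives about 1 in 20, or 5.95. KO replicate 2 was lowest for the companion layer and inner bulge list (5.52 mean log2 CPM). It was highest for Ly6a (56.0 CPM), Psmb8 (64.7 CPM), Btg2 (700.7 CPM) and Grik1 (0.178 CPM, from 2 counts). These 2 were all Grik1 counts of the KO group. Any count in a single library would have raised that flag, so it carries no weight. KO replicate 3 was highest for the cell-cell adhesion list (7.79) and lowest for Lfng (23.2 CPM) and Krt75 (2.83 CPM). KO replicate 1 was highest for the endothelial list (2.36), and KO replicate 5 was lowest for Cdh3 (76.6 CPM).

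The KO effect differed between stages, by the test of the difference itself, for 19 genes. The log2 fold change in early telogen minus that in anagen was 4.99 for Tgm5, 4.15 for Krt24, 4.06 for Wif1, 3.57 for Serpinb11 and 3.50 for Chat. It was 3.17 for Col6a1, 2.99 for Ccdc88c, 2.75 for Lgr6, 2.71 for Ctnnd2, 2.65 for Moxd1, 2.55 for Vwa2 and 2.55 for Mfap3l. It was 2.29 for Nrip3, 2.19 for Sms, 1.92 for Pros1, -2.39 for Enc1 and -1.86 for Ctsl. Each passed the test with all 12 libraries, whether or not the naming rule chose it. The calls for Tgm5, Krt24, Wif1, Serpinb11, Chat, Lgr6, Enc1 and Ctsl were each lost without some single libraries.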

How the results depend on the processing

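The early telogen result without KO replicate 2 and WT replicate 3 was chosen after seeing the data. Counts are given as higher and lower. Anagen KO against WT (0 and 0 by edgeR, 1456 at an unadjusted p under 0.05) gave 57 and 249 without a filter on low counts, 91 and 408 by DESeq2, 0 and 1 with sex as a covariate, 7 and 147 with all 12 libraries in 1 fit, and 46 and 207 with day as a block, which left 1 residual degree of freedom. Early telogen (60 and 55) gave 167 and 171 without a filter, 217 and 182 by DESeq2, 73 and 88 with sex as a covariate, 12 and 27 in the fit of all 12 libraries, 4 and 7 with replicate number as a block (1 residual degree of freedom), and 25 and 22 without the 2 libraries that stood apart. The difference between stages (17 and 2) gave 316 and 93 without a filter, 131 and 17 by DESeq2 and 6 and 0 with sex as a covariate (690 at an unadjusted p under 0.05). The WT stage counts (1724 and 2024) fell to 755 and 1286 with an added log2 fold change of at least 1, a stricter criterion by construction. For the others the cause was not tested. KO and WT libraries of early telogen that shared a number correlated at 0.106 and 0.0532 across genes, and other pairs at -0.141 to 0.124. In anagen those titled with the same day correlated at 0.414 and 0.359 and other pairs lower, so day may matter there, although 2 pairs are few, the values of the 2 KO libraries mirror each other by construction, and the age labels of the P31 pair differ.

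Lists called numbered 12 in anagen, 12 in early telogen, 8 for the difference and 6 by WT stage. With an estimated correlation they numbered 0 in each, and by fry 0, 1, 0 and 2. With sex as a covariate anagen gave 7 lists, and the mitosis list there turned to lower in KO (camera adjusted p = 0.941). Early telogen gave 7 lists with replicate number as a block and 4 without the 2 libraries, and WT stage gave 1 with a filter at 5 CPM. Each library left out in turn gave 0 to 14 and 0 to 81 genes in anagen, where a lone KO library is assumed to vary like the others. It gave 9 to 61 and 10 to 78 in early telogen, 0 to 51 and 0 to 4 for the difference, and 1055 to 1630 and 1257 to 1699 by WT stage. Lists called then numbered 10 to 17, 7 to 15, 7 to 12 and 3 to 8. Of the named genes' values under all alternatives, 65 of 5644 differed in sign with neither value called. Anagen had more counts per library than early telogen and still called fewer genes with 2 KO libraries, and low counts limit genes such as Grik1 in early telogen.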

Other observations

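In WT cells some cell-matrix adhesion and NOTCH pathway genes differed between stages, in lists that were not called as a whole. The laminin subunits Lama3 (1.74 ± 0.27 on the log2 scale) and Lamb3 (1.16 ± 0.17) and the integrin subunit Itga2 (3.25 ± 0.44) rose among 31 cell-matrix adhesion genes, of which 8 rose and 5 fell and 16 had negative log2 fold changes. Of 12 NOTCH pathway genes 4 rose and 0 fell, and 6 had negative log2 fold changes, with Notch2 at 1.33 ± 0.17, its ligand Jag1 at 1.30 ± 0.28, the modifier Lfng at 1.02 ± 0.18 and the transcription factor Rbpj at 0.84 ± 0.15. Neither list was called by camera (adjusted p = 0.520 and 0.455). Krt6a, a keratin of the inner bulge and of wounds, rose by 1.35 ± 0.23, while the growth factor Areg fell by 3.66 ± 0.63. Stage and table cannot be separated for these genes, and the share of other cells in the sort was not measured.

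The tests of gene kinds at 0 in 1 table were chosen after the result was seen, and the tests without shared libraries after that of the simulation below. Of the genes with a mean of at least 10 CPM in 1 table, 4 had 0 counts in all early telogen libraries, namely mmu-mir-6236, Hist1h2bm, Gm20594 and Dio3, and 0 had 0 counts in all anagen libraries. Counting of the opposite strand in 1 table only is argued against, since genes under a stronger gene on the opposite strand differed by -0.0968 log2 from genes without such overlap. Counting of both strands in 1 table stays open. Ambiguous reads are then given to no gene, and overlaps of any length were included, so the median may hardly move. Of the 4 genes 75% were not protein coding or of a kind with many copies, against 5.51% of genes as abundant (Fisher's exact p = 0.000637). The kinds were set after these genes were seen, so this p-value gives no support. Hist1h2bm and Gm20594 are protein coding and were counted by name, and mmu-mir-6236 had no match in the annotation. Whether annotation or the handling of reads with several positions differs between the tables stays open. Dio3, a thyroid hormone deiodinase gene, is of neither kind, and no biological explanation was tested for it.

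The KO effect ran against the WT stage effect in both stages, with genes that were higher in early telogen WT tending to be lower in KO (covariance across 13193 genes -0.213 in anagen and -0.390 in early telogen). Use of the same WT libraries in both effects is argued against as the whole cause, since simulated unchanged KO libraries gave 0.115 and -0.152, and the smaller distance was -33.2 SD of the simulations, an SD that is too small because genes were simulated as independent. With no library shared, the covariance stayed below 0 in 6 of 6 splits in each stage, with the highest at -0.188 in anagen and -0.132 in early telogen. Without 91 genes, those of the DNA replication and mitosis lists or correlated over 0.9 with Mki67, the part beyond the simulated value shrank by at most 9.21%. A cause in these 91 genes alone is argued against. Genes that follow the cell cycle less closely stayed in, so a wider effect of the cell cycle was not tested. An effect of Foxc1 on the stage of these cells, mice at different points of the hair cycle, and a sort that took other cells stay open and untested.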
